A study of Mus musculus with 12 samples.

How the data were processed

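Gene expression was measured in 12 samples of primary tumours from a mouse model of hepatocellular carcinoma, 3 in each of 4 groups. Per the labels' protocols, total RNA was extracted from formalin-fixed, paraffin-embedded tissue with a Qiagen miRNeasy FFPE kit. RNA from such tissue is fragmented, which short probes tolerate better than long amplicons do. The deposited values were whole-number counts per probe, not normalised, for 784 probes: 770 genes, 6 positive controls and 8 negative controls. Those control probes are of the kind used on digital counting panels with colour-coded probes. The counting instrument, the panel's name and the software that made the counts are not given in the sources used here. No background had been subtracted as far as the values show, since the negative controls still held counts. Of the 770 gene names, 754 were current symbols of the mouse GRCm38.p6 gene table, 8 were synonyms in it and 8 matched nothing there; names are printed as deposited. Probes for members of close gene families (Klra, H2, Ifit, Ccl21 and the like) can pick up near-identical copies, so single members of these families are uncertain.

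Groups were taken from the labels: isotype antibody, dICB (anti-PD-1 with anti-CTLA4 antibody), dICB with Dexa at 10 mg, and dICB with Dexa at 200 mg. The labels give the doses in mg with no body weight or schedule, do not spell Dexa out, and hold no group with Dexa alone. They do not state that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may in part be technical. A code in the labels reads ICI7 or ICI10 and its meaning is not stated. All 3 isotype samples carried ICI7 and all 3 dICB samples ICI10. The 10 mg group had 2 samples coded ICI7 and 1 coded ICI10, and the 200 mg group 1 and 2. The code was treated as a possible batch.

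Total counts over genes ran from 252994 to 428944 per sample. The mean negative control count ran from 11.1 to 24.4, and the background limit of a sample, that mean plus 2 standard deviations, from 18.1 to 38.1 counts. Between 549 and 604 of the 770 genes lay above it. Because background was left in, fold changes of genes near it are understated. Samples of one group differed by far more than counting error, with a chi-square per degree of freedom of at least 4.05; this does not show whether they came from separate tumours.

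Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with a mean of at least 20 counts over the 12 samples were tested (635 genes; 135 were not), and control probes were left out. Library sizes were scaled by TMM, which takes most genes as unchanged. One quasi-likelihood model with a mean per group was fitted over all 12 samples, so that 8 residual degrees of freedom, 12.4 after moderation, gave the spread. The common biological coefficient of variation was 28.3%. The 7 comparisons were tested two-sided with Benjamini-Hochberg adjustment at 0.05 over the 635 genes of each. Every adjusted p of a gene in the report comes from this edgeR test unless another tool is named. Standard errors of log2 fold changes were taken as the size of the log2 fold change over the square root of its F value, which is approximate. Normalised counts are counts scaled to the mean effective library of 357600.

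Gene lists were fixed from textbook markers: cell types of tumour tissue, responses to interferon, antigen presentation, NF-kB, glucocorticoid and others. Of 23 lists, 21 entered the list test. Proliferation genes had only 2 tested members and no value is given for them, and 20 housekeeping genes were kept apart. The test was fry in limma 3.58.1 on log2 counts scaled by library size with a prior count of 2, adjusted over the 21 lists. It asks whether the genes of a list move, on balance, one way, and compares them with no other genes; its mixed form asks whether they change in either direction. Camera, which compares a list with the other genes, was run with a preset correlation of 0.01 and with an estimated one. A list score is the mean over members of those log2 values after centring each gene on its mean over all samples.

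Named genes followed a rule. Up to 12 genes that rose and 12 that fell past the threshold were taken by fold change, with no overlap between groups. Where fewer than 5 passed in a direction, the 5 of smallest p stood in for them and are given as values. Up to 4 genes of smallest p were added from each list, and always Pdcd1, Ctla4 and Cd274. Some genes the rule named were left out of the text, most of them for length, after their values had been seen. Genes named outside the rule are said to be so.

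The groups, comparisons, tests, lists, rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, housekeeping gene factors, no filter or a mean of at least 50 counts, a prior count of 16, robust moderation, a fit of the compared groups alone, the replicate number as a block, the sample code as a covariate, samples of 1 code alone, both forms of camera, and each sample left out in turn. Chosen after seeing the data were positive control factors, background-subtracted values tested with limma, the omission of dICB replicate 1 from comparisons that do not contain it, the omission of that sample together with Dexa 10 mg replicate 2, and camera and the counts adjusted over a list alone without dICB replicate 1.

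The procedure was tested on simulated counts of the 635 genes for the Dexa 200 mg and isotype groups, with 200 genes changed in each of 5 runs. The edgeR test recovered 64% of genes changed by a fold of 2 and 96.4% of those changed by a fold of 4, and 3.14% of its calls were false. For DESeq2 these were 71%, 97.2% and 4.97%, and for limma 63.2%, 96.2% and 2.81%. A macrophage list raised by a fold of 2 was called in 5 of 5 runs, with 1 call among 100 tests of other lists, but simulated genes were independent of each other, which real genes are not. In the runs on genes as many rose as fell, which suits TMM. Counts were drawn from the spread that edgeR had fitted, with no code effect and no sample that stood apart. The rates of false calls therefore need not hold for the real comparison. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.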

Results

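The series asks how corticosteroid premedication bears on the antitumour effect of immune checkpoint blockade in mouse models of hepatocellular carcinoma. A panel of 770 genes, largely of the immune system, was counted in 12 primary tumour samples: 3 from isotype antibody, 3 from dICB, 3 from dICB with Dexa at 10 mg and 3 from dICB with Dexa at 200 mg. Total counts over genes were 305347 to 357771 in the isotype samples, 252994 to 428944 in dICB, 397145 to 417274 in the 10 mg group and 262314 to 425712 in the 200 mg group. Levels below are normalised counts as mean ± SD, with n = 3 per group unless stated, and changes are log2 fold changes ± SE.

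Replicate 1 of dICB stood apart from all others in neutrophil and inflammatory genes. It held 15820 normalised counts of S100a8, a calcium-binding protein abundant in neutrophils, where the other 11 samples held 165 to 484. The cytokine Il1b stood at 3386 there and between 71.7 and 148 elsewhere, and Lcn2, a granule protein, at 1819. Its score was 2.51 on the neutrophil list and 1.63 on the NF-kB list (log2 units from the mean of all samples). Replicate 2 of the 10 mg group differed in other genes. It held 5408 counts of the cytokine Mif, 1441 of Cd99, 28.9 of the transcription factor Jun and 34.4 of the Fc receptor Fcgr3, the 4 being picked after their values were seen.

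The comparison of dICB with isotype asks what the antibodies changed. All isotype samples were coded ICI7 and all dICB samples ICI10, so antibodies and code cannot be told apart between these groups. Nos2 and Arg1, both on the macrophage list, had the smallest p, though no gene passed the threshold. Nos2, the inducible nitric oxide synthase, stood at 268 ± 119.5 under dICB and 62.1 ± 0.65 under isotype (log2 fold change 2.11 ± 0.38), and Arg1, the liver-type arginase that hepatocytes as well as macrophages make, was 1.66 ± 0.32 higher, both with an adjusted p of 0.0593. The scavenger receptor Marco was 2.21 ± 0.50 higher (1.45 without dICB replicate 2) and the beta-glucan receptor Clec7a 1.16 ± 0.26. Cd274, which encodes PD-L1, stood at 1681 ± 211 against 747 ± 23.04 (1.17 ± 0.28, adjusted p = 0.0992).

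Other genes named by the rule did not pass either. The protease Gzmb of cytotoxic cells was 1.13 ± 0.33 higher (0.75 without dICB replicate 2), the interferon-induced genes Gbp5 and Cxcl9 were 0.57 ± 0.17 and 0.54 ± 0.20 higher, and the MHC class I gene H2-K1 was 0.63 ± 0.23 higher. Lower values were found for the nuclear pore gene Nup107 (-0.92 ± 0.24), the epithelial adhesion gene Epcam (-0.85 ± 0.23), Hmgb1 (-0.85), the apoptosis gene Bax (-0.84), Psmd7 (-0.76), Sf3a3 (-0.74) and the T cell transcription factor Tcf7 (-0.88 ± 0.46, adjusted p = 0.298). Housekeeping genes moved with these: 19 of 20 were lower, with a median of -0.49, or -0.31 with positive control factors and, by construction, near 0 with housekeeping gene factors. The antibody targets showed no change past the threshold, with Pdcd1 at -0.24 ± 0.36 (-0.53 without dICB replicate 2, -0.05 without replicate 3) and Ctla4 at 0.27 ± 0.25 (0.09 without dICB replicate 1, 0.42 without replicate 3). Log2 fold changes of 4.36 for S100a8, 4.55 for Lcn2, 3.64 for Il1b and 3.77 for the prostaglandin synthase Ptgs2 rested on dICB replicate 1. They were -0.06, -0.07, 0.39 and 0.68 without it. Fpr2 at 1.89 and Il1rn at 1.76 were 1.39 and 0.86 without that sample.

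With edgeR 0 of 635 genes passed, 127 had an unadjusted p under 0.05 (77 higher, 50 lower; 31.75 expected by chance), and 144 had no overlap between the groups (22.7%, where chance gives 10%). DESeq2 passed 30 genes, 20 higher and 10 lower, and background-subtracted values with limma passed 2, Nos2 and Arg1. Among the 21 lists 0 shifted by fry, with 3 at an unadjusted p under 0.05. Camera passed 2 lists with the preset correlation (macrophage and glucocorticoid-induced genes, both higher) and 0 with an estimated one. The glucocorticoid-induced score was 0.92 in dICB replicate 1 and -0.002 and -0.09 in the other dICB samples, and without that replicate the list did not pass (adjusted p = 0.211 by camera with the preset correlation), while the macrophage, MHC class II and cytotoxic effector lists did, as higher, and 0 lists did with an estimated correlation (adjusted p = 0.583 for each of these 3). The macrophage list had an adjusted p of 0.238 by fry and 0.00518 in its mixed form; adjusted over the list alone, 9 of its 26 members rose and 1 fell. In the same way 5 of 8 neutrophil genes and 9 of 26 NF-kB genes rose, lists on which dICB replicate 1 stood apart; without it 0 and 1 rose, and 5 macrophage genes. With housekeeping gene factors 45 genes passed, all higher, and the lists shifted numbered 8. These factors moved the median of all genes up, which adds to any rise whatever its cause. As fry compares a list with no other genes, neither count is separate evidence of a response. The count of genes was 42 without dICB replicate 3 and 10 without dICB replicate 2, fits in which dICB replicate 1 weighed more. Replicate 3 of dICB was also close to isotype. Its log2 counts correlated at 0.969 to 0.971 with isotype samples and at 0.900 and 0.956 with dICB replicates 1 and 2. Its macrophage score was -0.19, against 0.29 and 0.34 in those 2. What made the count larger without it was not tested. Without dICB replicate 3, 2 lists shifted. No code in the labels held both groups. With the code as a covariate, which the Dexa groups make possible, 0 genes passed in edgeR and 81 had an unadjusted p under 0.05. The effect of the code in that fit came only from splits of 2 samples against 1 within each Dexa group. At 10 mg the 1 sample was replicate 2, which stood apart.

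**Figure D1:**
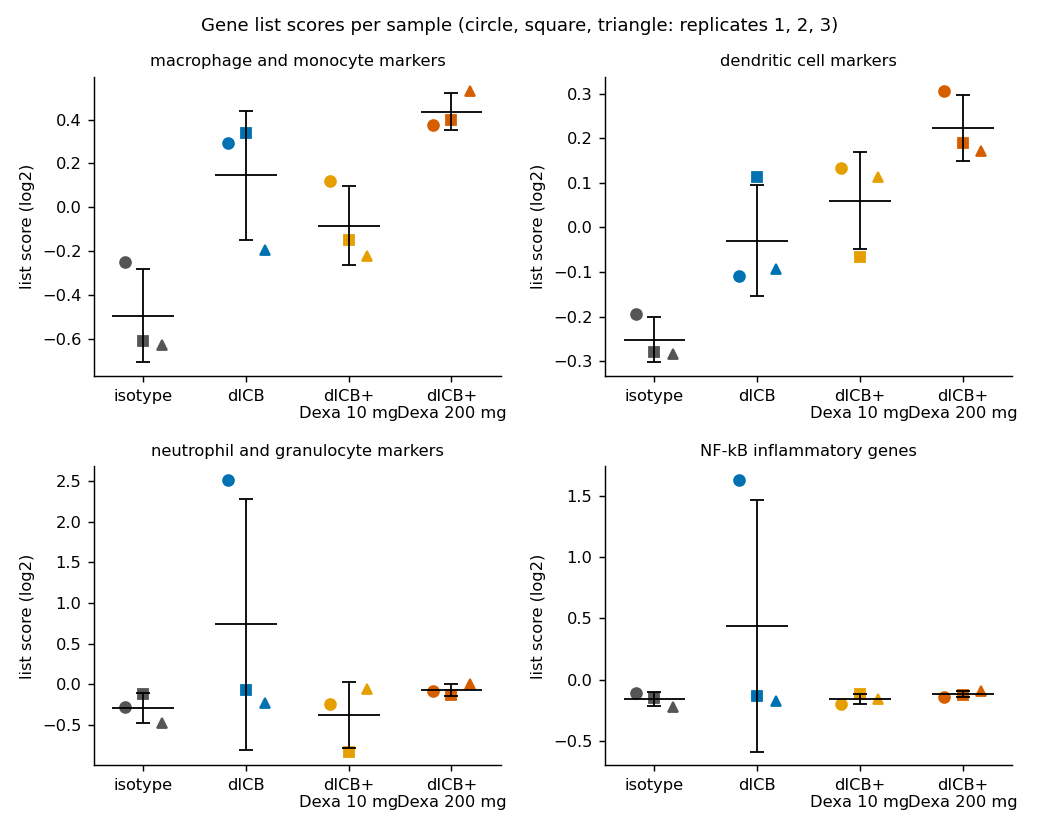
List scores per sample for 4 gene lists (log2, centred on the mean of all samples), with group means (line) and SD (bars) of 3 samples each. Replicate 1 of dICB, the circle, reached 2.51 on the neutrophil list. On the macrophage list the mean was 0.43 ± 0.08 in Dexa 200 mg samples, 0.15 ± 0.29 in dICB and -0.50 ± 0.21 in isotype.

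The comparison of dICB with Dexa at 10 mg against dICB alone asks what the lower dose changed under the antibodies. Ccl17, a chemokine for T cells made by dendritic cells, stood at 166 ± 109 against 71.7 ± 20.1 (1.20 ± 0.44, but 0.52 without Dexa 10 mg replicate 2), and A2m, a protease inhibitor, was 1.17 ± 0.35 higher. The matrix protease Mmp9 stood at 58.5 ± 4.64 against 113.9 ± 41.0 (-0.96 ± 0.29), and Arg1 was at -0.98 ± 0.31. Psmd7 was 0.53 ± 0.17 higher. Of 20 housekeeping genes 18 were higher, with a median of 0.23, or 0.38 with positive control factors. Ctla4 was at -0.58 ± 0.25, Cd274 at -0.27 ± 0.27 (-0.70 without Dexa 10 mg replicate 2, -0.03 without replicate 3) and Pdcd1 at 0.21 ± 0.36. Without dICB replicate 1 Mmp9 was at -0.61 and Ctla4 at -0.37. None of these passed, the smallest adjusted p being 0.402.

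Several inflammatory genes were far lower: Il1b -3.71 ± 1.02, the neutrophil chemokine Cxcl2 -4.04 ± 1.18, S100a8 -4.22 ± 1.30, Mefv -1.83, Trem1 -1.59 and Il1rn -1.29. Without dICB replicate 1 these were -0.43, 0.09, 0.22, -0.61, -0.48 and -0.37. By edgeR 0 of 635 genes passed and 60 had an unadjusted p under 0.05 (25 without dICB replicate 1); DESeq2 and limma on background-subtracted values also passed 0. Groups did not overlap in 50 genes (7.87%, chance 10%). By fry 0 of 21 lists shifted and 0 had an unadjusted p under 0.05, where camera passed 3 with the preset correlation (neutrophil, NF-kB and endothelial genes, all lower) and 0 with an estimated one. Adjusted over the list alone, 7 of 8 neutrophil genes and 8 of 26 NF-kB genes fell. These falls rested on dICB replicate 1: without it 0 genes of either list fell, and camera passed only the endothelial list with the preset correlation and 0 lists with an estimated one (adjusted p = 0.874). The 11 tested genes of the glucocorticoid-induced list did not shift (adjusted p = 0.698); 10 were lower, but 4 without dICB replicate 1. Without dICB replicate 2, where dICB replicate 1 weighed more, 1 gene passed, Cxcl14 at -2.16, which the rule does not name. Samples coded ICI10 hold 1 sample of the 10 mg group, replicate 2, which stood apart. The mast cell markers were lower in a fit of that code, with a score of -0.49 in that sample. The other 10 mg samples had scores of 0.14 and -0.14.

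At 200 mg against dICB alone, Mmp9, Ccl19 and Ccl17 had the smallest p, and no gene passed. Ccl17 stood at 260.3 ± 125.5 against 71.7 ± 20.1 (1.85 ± 0.45), and Ccl19, which draws T cells and dendritic cells, at 166 ± 14.4 against 80.5 ± 24.8 (1.03 ± 0.24). Ccl11 was 1.11 ± 0.32 higher, Ccl8 1.26 ± 0.39 (0.61 without Dexa 200 mg replicate 3), the monocyte chemokine receptor Ccr2 0.87 ± 0.29, the kinase Prkcd 0.67 ± 0.22 and Chil3, a chitinase-like protein of alternatively activated macrophages, 1.53 ± 0.56 (0.78 without Dexa 200 mg replicate 2). Mmp9 stood at 45.7 ± 15.2 against 113.9 ± 41.0 (-1.30 ± 0.30) and the angiogenic factor Vegfa was at -0.85 ± 0.23. Ctla4 was at -0.72 ± 0.25, Cd274 at -0.29 ± 0.27 and Pdcd1 near no difference at -0.003 ± 0.36.

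By edgeR 0 genes passed (smallest adjusted p 0.267), 54 had an unadjusted p under 0.05, and 56 did not overlap (8.82%, chance 10%). DESeq2 passed 3, Ccl17, Ccl19 and Mmp9, and limma on background-subtracted values 0. Il1b (-3.37), S100a8 (-4.06) and Cxcl2 (-4.13) were at -0.11, 0.36 and 0.00 without dICB replicate 1, while Ccl17 was at 1.68 and Mmp9 at -0.95. By fry 0 lists shifted and 1 had an unadjusted p under 0.05, the dendritic cell list (adjusted p = 0.680 by fry in limma). Camera passed 5 with the preset correlation (macrophage and MHC class II genes higher; neutrophil, NF-kB and endothelial genes lower) and 0 with an estimated one. Adjusted over the list alone, 1 dendritic cell gene rose, 4 neutrophil genes and 6 NF-kB genes fell. Without dICB replicate 1 these were 0, 0 and 0, and camera passed only the macrophage and endothelial lists with the preset correlation and 0 lists with an estimated one (adjusted p = 0.983 for both). The glucocorticoid-induced list did not shift (adjusted p = 0.819), with 9 of 11 genes lower, or 6 without dICB replicate 1. Without dICB replicate 2, where dICB replicate 1 weighed more, there were 8 genes, all lower. They included Lcn2 at -4.78, Cxcl2 at -4.68, Mmp9 at -1.53 and Vegfa at -1.08. Among samples coded ICI10 0 genes passed in edgeR and 20 had an unadjusted p under 0.05.

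**Figure D2:**
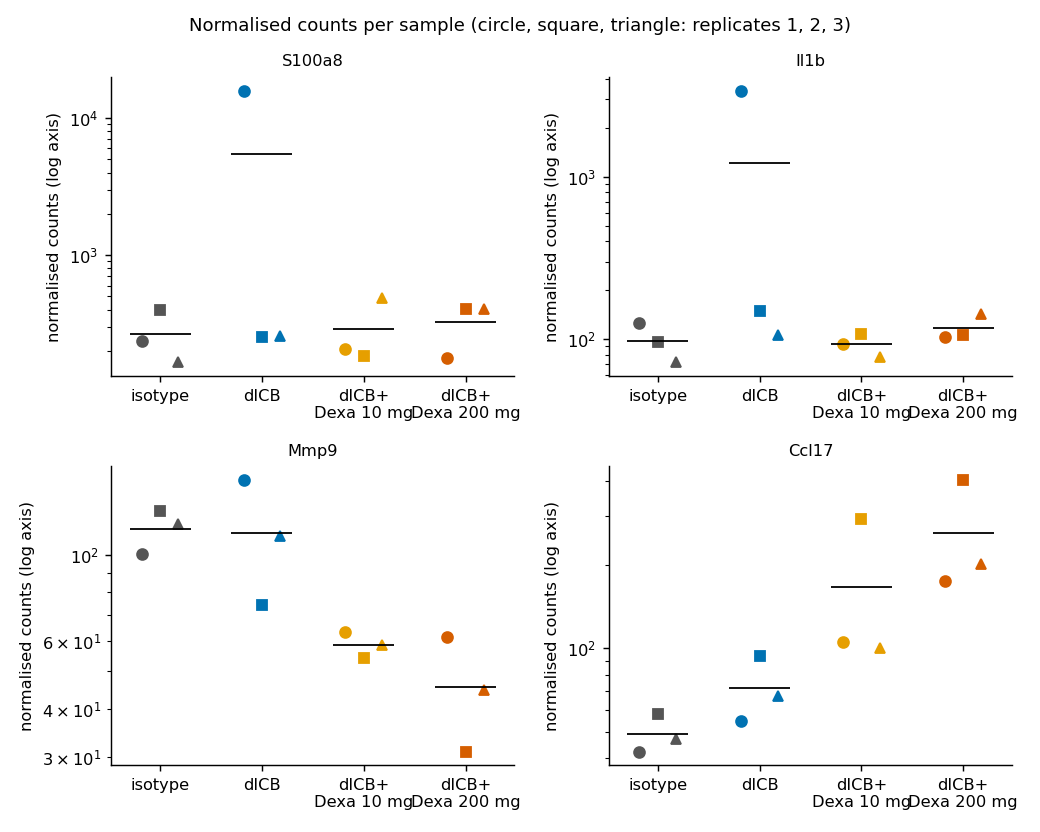
Normalised counts of S100a8, Il1b, Mmp9 and Ccl17 per sample on log axes, with the group mean as a line. S100a8 reached 15820 in replicate 1 of dICB and at most 484 in the other samples, and Mmp9 ran from 31.0 to 63.3 in the 6 samples given Dexa, below all samples of the other groups.

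Set against the 3 samples of dICB, both doses as the mean of the 2 groups (6 samples) had Mmp9 lower and Ccl17 higher without passing, at -0.78 and 1.38 without dICB replicate 1. Mmp9 stood at 52.1 ± 12.3 (n = 6) against 113.9 ± 41.0 (-1.13 ± 0.25, adjusted p = 0.123) and Ccl17 at 213 ± 117 (n = 6) against 71.7 ± 20.1 (1.53 ± 0.40, adjusted p = 0.147). Ctla4 was at -0.65 ± 0.21, Cd274 at -0.28 ± 0.23 and Pdcd1 at 0.10 ± 0.31. Il1b, Cxcl2, S100a8 and Lcn2 lay between -3.54 and -4.14, and without dICB replicate 1 at -0.27, 0.05, 0.29 and 0.55. The decoy receptor Il1r2, a glucocorticoid-induced gene, was at -0.98 ± 0.36, and at -0.04 without that sample. Cfd, an adipocyte protease, was 4.18 ± 1.69 higher, but 1.97 without Dexa 10 mg replicate 3 and 2.41 without Dexa 200 mg replicate 1.

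By edgeR 0 genes passed and 53 had an unadjusted p under 0.05 (16 without dICB replicate 1); 14 did not overlap (2.20%, where chance gives 2.38%). DESeq2 passed 2, Ccl17 and Mmp9, and limma on background-subtracted values 0. By fry 0 of 21 lists shifted and 0 had an unadjusted p under 0.05. Camera passed neutrophil, NF-kB and endothelial genes as lower, 3 lists, with the preset correlation and 0 with an estimated one. Adjusted over the list alone, 6 neutrophil genes and 12 NF-kB genes fell and 1 dendritic cell gene rose. Without dICB replicate 1 these were 0, 0 and 0, and camera passed only the endothelial list with the preset correlation and 0 lists with an estimated one (adjusted p = 0.988). The glucocorticoid-induced list had an adjusted p of 0.789, with 8 of 11 genes lower, or 4 without that replicate. The count of genes was 24 without dICB replicate 2 and 15 without dICB replicate 3, fits in which dICB replicate 1 weighed more. Samples coded ICI10 hold 1 sample at 10 mg, replicate 2, which stood apart, so a fit of that code rests on it there.

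Between the doses, genes of the macrophage list were higher at 200 mg than at 10 mg without passing the threshold. Arg1 stood at 1461 ± 326 against 585 ± 256 (1.32 ± 0.31, adjusted p = 0.299) and Chil3 was 1.90 ± 0.57 higher (1.09 without Dexa 200 mg replicate 2). Ccl19 was 1.01 ± 0.24 higher, the lectin receptor Clec5a 0.78 ± 0.22, the interferon-stimulated gene Ifit1 1.09 ± 0.31 (0.68 without Dexa 200 mg replicate 3) and the T cell chemokine receptor Cxcr3 0.97 ± 0.31. Lower at 200 mg were the Ly49 family gene Klra17 (-1.31 ± 0.35), the growth factor receptor Egfr (-0.88), the ribosomal gene Rpl19 (-0.85, or -0.55 without Dexa 10 mg replicate 2), fibronectin, Fn1 (-0.81), Dusp6 (-0.80) and Sf3a3 (-0.61). Of 20 housekeeping genes, Sf3a3 among them, 17 were lower at 200 mg, with a median of -0.34, or -0.29 with positive control factors. Pdcd1 at -0.21 ± 0.36, Ctla4 at -0.14 ± 0.26 and Cd274 at -0.02 ± 0.27 showed no direction that held across settings.

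By edgeR 0 genes passed, 76 had an unadjusted p under 0.05 and 138 did not overlap (21.7%, chance 10%). DESeq2 passed 2, Arg1 and Ccl19, and limma on background-subtracted values 0. By fry 0 of 21 lists shifted and 1 had an unadjusted p under 0.05: the macrophage list (adjusted p = 0.542 by fry in limma), with 23 of 26 members higher and 3 rising adjusted over the list alone. Camera passed that list alone, 1 of 21, with the preset correlation and 0 with an estimated one. Klra17 and 1 epithelial gene, Egfr, fell adjusted over the list alone. Without both samples that stood apart 2 genes passed, Arg1 and Klra17. Among samples coded ICI7, with 1 sample at 200 mg, Arg1 was at 1.72. Samples coded ICI10 hold 1 sample at 10 mg, replicate 2, which stood apart, so a fit of that code rests on it there.

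Against isotype, the 10 mg group was higher in macrophage and dendritic cell genes, again short of the threshold. Nos2 stood at 185 ± 67.1 against 62.1 ± 0.65 (1.57 ± 0.37, adjusted p = 0.340) and Ccl17 at 166 ± 109 against 49.0 ± 7.90 (1.76 ± 0.45). Chil3 was 2.10 ± 0.60 higher, the chemokines Ccl9 and Ccl22 1.43 ± 0.37 and 1.18 ± 0.31, the costimulatory gene Cd86 0.79 ± 0.22, Gzmb 0.94 ± 0.33 and Cd274 0.90 ± 0.27. Without Dexa 10 mg replicate 2 Cd274 was at 0.45, Gzmb at 0.54 and Ccl17 at 1.05. Lower were Mmp9 (-0.99 ± 0.29), Ccl21a (-1.12, at background in all samples at 10 mg) and Mcam (-0.66, or -0.37 without isotype replicate 1). Of 20 housekeeping genes 17 were lower, with a median of -0.32, or -0.03 with positive control factors. Ctla4 was at -0.32 ± 0.25 and Pdcd1 at -0.03 ± 0.36. By edgeR 0 genes passed, 53 had an unadjusted p under 0.05 and 83 did not overlap (13.1%, chance 10%). DESeq2 passed 4, all higher: Nos2, Ccl17, Ccl9 and Chil3. Limma on background-subtracted values passed 0. By fry 0 lists shifted and 1 had an unadjusted p under 0.05, the dendritic cell list (adjusted p = 0.124), in which 3 genes rose adjusted over the list alone. Camera passed 4 lists as higher with the preset correlation (macrophage, dendritic cell, MHC class II and interferon-gamma genes) and 0 with an estimated one. The dendritic cell list was the 1 list to shift among samples coded ICI7, where 0 genes passed in edgeR and 69 had an unadjusted p under 0.05, and again without both samples that stood apart.

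Samples given dICB with Dexa at 200 mg differed from isotype samples in 84 of 635 genes, of which 39 rose and 45 fell. These calls were not stable: 0 genes passed in edgeR without isotype replicate 3. With the sample code as a covariate 26 of the 84 still passed, and the split of rises and falls depended on scaling, as given below. Chil3 rose from 40.2 ± 6.96 to 648 ± 461 (4.01 ± 0.64, adjusted p = 0.00665), Nos2 from 62.1 ± 0.65 to 342 ± 112 (2.46 ± 0.38, adjusted p = 0.00665) and Arg1 from 364 ± 83.2 to 1461 ± 326 (2.00 ± 0.32, adjusted p = 0.00665). Lyz2, the lysozyme of myeloid cells, rose from 7186 ± 4544 to 23850 ± 6142 (1.73 ± 0.45). The neutrophil chemokine Cxcl15 fell from 534 ± 174 to 116 ± 53.8 (-2.19 ± 0.44, adjusted p = 0.0144) and the transcription factor Myc from 1680 ± 323 to 787 ± 113 (-1.09 ± 0.22, adjusted p = 0.0154).

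Macrophage genes were prominent among the named rises. The macrophage score was 0.43 ± 0.08 at 200 mg, 0.15 ± 0.29 in dICB alone and -0.50 ± 0.21 in isotype. Much of the difference from isotype was thus seen in dICB alone, and by fry 0 lists shifted between 200 mg and dICB. Of 26 macrophage and monocyte markers 11 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone. Besides Chil3, Nos2, Arg1 and Lyz2 these included Marco (2.27 ± 0.51; at background in 2 isotype samples), Clec7a (1.46 ± 0.27) and the lysosomal protease Ctss (1.47 ± 0.41); the fractalkine receptor Cx3cr1 fell (-1.19 ± 0.26). The list shifted upward by fry (adjusted p = 0.0116), with an adjusted p = 0.404 with an estimated correlation in camera. Of 16 dendritic cell markers 3 rose: Ccl17 (2.40 ± 0.46), Ccl22 (1.61 ± 0.31) and Cd86 (0.79 ± 0.22), with 4 adjusted over the list alone; Itgax, at 0.87 ± 0.27, had an adjusted p of 0.0512 and was at 0.57 without Dexa 200 mg replicate 2. Ccl17 and Ccl22 are chemokines that macrophages make as well. That list also shifted upward (adjusted p = 0.0116), with an adjusted p = 0.404 with an estimated correlation, and did not pass with the preset one. Chemokines that rose outside these lists were Ccl9 (2.07 ± 0.38), Ccl11 (2.02 ± 0.33), Ccl6 (1.92 ± 0.32) and Ccl8 (1.81 ± 0.39, but 1.16 and short of the threshold without Dexa 200 mg replicate 3). The formyl peptide receptor Fpr2 rose by 1.64 ± 0.48 and Slamf7 by 1.61 ± 0.37. Ccl8 was not the least stable of these calls. Over 7 fits that each left out 1 sample, Ccl8 lost the threshold in 3. Slamf7, Lyz2 and Marco lost it in 4, Ctss and Cd86 in 5 and Fpr2 in 6, but Chil3, Nos2, Arg1 and Clec7a in 1.

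In lymphocyte lists few genes changed. Among 12 cytotoxic effector genes Gzmb rose (1.28 ± 0.33), 1 also adjusted over the list alone, and among 13 genes of the NK list 2 of the Ly49 family fell, Klra17 (-1.40 ± 0.35), which is known from plasmacytoid dendritic and myeloid cells more than from NK cells, and Klra4 (-0.80 ± 0.19), 2 also adjusted over the list alone. No gene passed, in edgeR over all genes or adjusted over the list alone, among 16 T cell, 6 regulatory T cell, 13 checkpoint, 7 B cell and 4 mast cell genes, of which 1, 1, 4, 1 and 0 had an unadjusted p under 0.05. Ctla4 was at -0.46 ± 0.26, Pdcd1 at -0.24 ± 0.36 and Cd274 at 0.88 ± 0.27 (adjusted p = 0.0512). Of 12 T helper genes Il12rb2 rose (1.03 ± 0.30; at background in all 3 isotype samples) and 0 passed in edgeR adjusted over the list alone.

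More interferon and MHC class II genes were higher than lower: 18 of 23 interferon-gamma genes, 17 of 26 type I interferon genes and all 10 MHC class II genes. Gbp5 (0.77 ± 0.17) and Cxcl9 (0.83 ± 0.20) rose among the interferon-gamma genes, and Irf7 (1.07 ± 0.27) and Ifit2 (0.92 ± 0.21) among the type I genes, 2 in each list adjusted over the list alone. Of the MHC class II genes Ctss rose, and 5 did adjusted over the list alone, H2-Ab1 standing at 0.69 ± 0.23 with an adjusted p of 0.0633. These 3 lists each had an adjusted p of 0.136 by fry; the MHC class II list passed by camera with the preset correlation and not with an estimated one. The MHC class I list had 9 of 15 genes higher, a mean log2 fold change of -0.038 and an adjusted p of 0.993 by fry. Of its genes H2-K1 rose (0.93 ± 0.23) and 2 fell, among them the proteasome gene Psmd7 (-0.76 ± 0.17), counts that were the same adjusted over the list alone.

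Epithelial genes were among those that fell. The epithelial score was 0.21 in isotype, -0.11 in dICB alone and -0.16 at 200 mg. Of 5 epithelial genes 2 fell, Epcam (-0.84 ± 0.23) and Egfr (-0.94 ± 0.27), also 2 adjusted over the list alone (adjusted p of the list 0.128 by fry). The transferrin receptor Tfrc (-1.29 ± 0.32), the mitochondrial protein gene C1qbp (-1.18 ± 0.27), Nup107 (-1.06 ± 0.24) and the NK ligand H60a (-1.08 ± 0.30) fell too. Il11 (-1.65 ± 0.32) and Il7 (-1.10 ± 0.27) fell, as did Klra17, to background in all 3 samples, so their folds are understated. Of 20 housekeeping genes 19 were lower, with a median of -0.56, or -0.20 with positive control factors; housekeeping gene factors set that median near 0 by construction. Among them 6 fell, including Polr1b (-1.17 ± 0.28), the deacetylase Hdac3 (-0.90 ± 0.21) and Sf3a3 (-0.82 ± 0.19), 1 rose, and 9 fell and 1 rose adjusted over the list alone. Of 26 NF-kB genes Nos2 rose and Lif (-0.88 ± 0.25) and Nfkb2 (-0.80 ± 0.22) fell, the same 1 and 2 adjusted over the list alone. Of 8 neutrophil genes Fpr2 rose and Mmp9 (-1.33 ± 0.30) fell, 1 and 1 also adjusted over the list alone. Among 15 complement genes C4b rose (0.93 ± 0.26), with 0 in edgeR adjusted over the list alone, and among 12 fibroblast genes Ccl11 rose, with 2 rising and 1 falling adjusted over the list alone. No gene of 18 endothelial and 11 glucocorticoid-induced genes passed in edgeR, over all genes or adjusted over the list alone; 4 and 3 had an unadjusted p under 0.05. Apart from the macrophage and dendritic cell lists, the adjusted p by fry of the 21 lists was at least 0.128, and 6 lists had an unadjusted p under 0.05; in the mixed form 11 lists passed.

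All 84 genes had no overlap between the groups, as did 283 of the 635 tested (44.6%, chance 10%), and 205 had an unadjusted p under 0.05. DESeq2 passed 123 genes, 80 of the 84 among them, and limma on background-subtracted values 77, of which 74 were among the 84. The split of 39 rises and 45 falls depended on scaling: with housekeeping gene factors, which raised the median of all genes to 0.55, it was 161 and 5, and with positive control factors 55 and 2. The code entered as a covariate left 29 genes (18 rose, 11 fell), and samples coded ICI7 alone, with 1 sample at 200 mg assumed to vary like the rest, gave 148 genes (75 rose, 73 fell), with 70 of the 84 among them, but 0 lists by fry with 3 at an unadjusted p under 0.05. Fits of the compared groups alone gave 181 genes, and the omission of both samples that stood apart 169. The count of genes was 0 without isotype replicate 3 (edgeR), 13 without isotype replicate 2, 11 without Dexa 200 mg replicate 2 or without replicate 3, and 50 without replicate 1. Lists shifted numbered 0 without isotype replicate 2 or 3 and 1 without Dexa 200 mg replicate 3. Over 7 fits that each left out 1 sample, dICB replicate 1 among them, Lif and Il12rb2 lost the threshold in 6. C4b, H2-K1, Egfr, Epcam, Tfrc, Il7, Klra17, Klra4 and Nfkb2 lost it in 5.

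**Figure D3:**
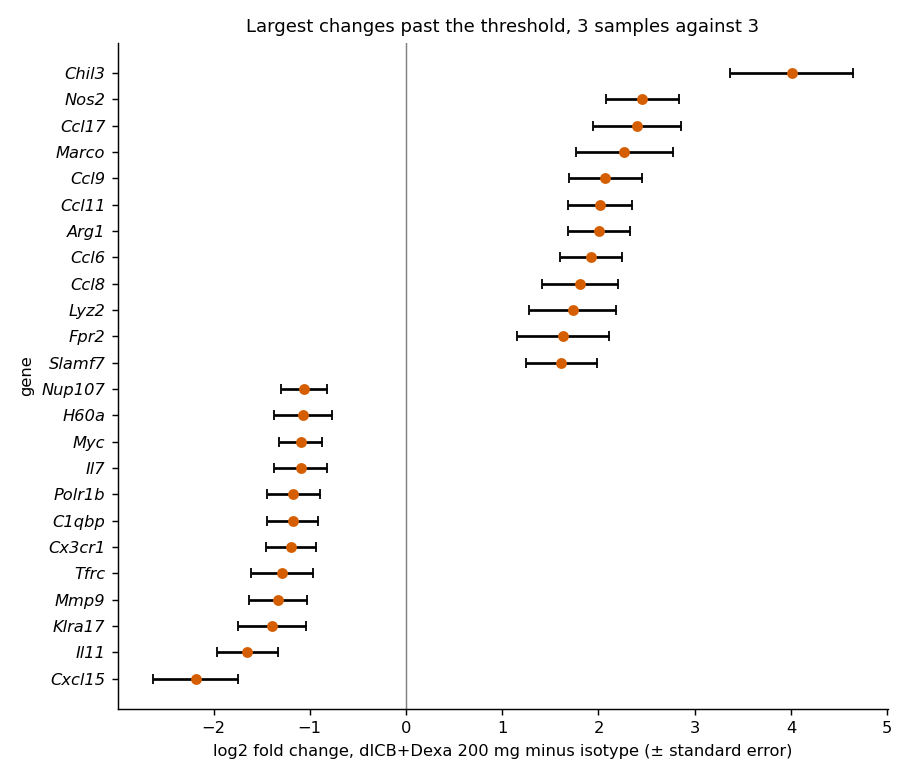
Log2 fold changes (points) with standard errors (bars) of the 12 genes with the largest rise and the 12 with the largest fall past the threshold, Dexa 200 mg against isotype, 3 samples each. Values ran from 4.01 for Chil3 to -2.19 for Cxcl15; with housekeeping gene factors the falls of most genes no longer passed.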

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

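All tests on dICB replicate 1 given here were chosen after its values had been seen. One gene outside the 635 tested stood at over 2 times the background limit of a sample with no isotype sample above its own limit: Csf3, the granulocyte growth factor, had 111 counts in dICB replicate 1, where the background limit was 33.8. The highest isotype sample had 17 counts and the highest of the remaining samples 18. It was picked out as a signal in genes left out of the comparisons, above the level in the control samples, and was the 1 such gene among 135.

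Csf3 belongs to a wider pattern in that sample, in which the 34 tested members of the neutrophil and NF-kB lists lay a median of 1.52 (log2; quartiles 0.40 and 3.22) above the other dICB samples. A difference in library size or scaling is argued against, since the other 601 genes lay at a median of -0.07, which leaves a gap of 1.59. An action of the antibodies alike in all dICB samples would have raised the other dICB samples too. These lay only 0.038 above the isotype mean on the score of both lists, where this sample lay 2.03 above and the isotype SD was 0.08. As the lists were taken up for standing apart in this sample, that restates the pattern and is no separate evidence. RNA from neutrophils in this piece of tissue is a candidate explanation, as 7 of 8 neutrophil genes had their highest level of all samples there, against 12 of 26 NF-kB genes and 86 of the 635 tested, though the neutrophil list is itself part of the pattern. Whether an infected or necrotic area, a response of a single animal or the handling of the block lay behind it was not tested.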

How the results depend on the processing

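Positive control factors, background subtraction with limma and the omission of both samples that stood apart (dICB replicate 1 and Dexa 10 mg replicate 2), as well as that of dICB replicate 1 where it is not compared, were chosen after seeing the data. The cause of a change was not tested except where stated. Over the alternatives that keep all samples or leave out a set of them, 1485 values of named genes kept direction and side of the threshold, 73 no longer passed, 77 newly passed and 38 changed sign; with single samples left out these were 726, 166, 36 and 28. Housekeeping gene factors moved the median of all genes to 0.46 for dICB against isotype, 0.55 for Dexa 200 mg and 0.23 for Dexa 10 mg against isotype, -0.19 for Dexa 10 mg against dICB and 0.32 between the doses. Positive control factors moved it to 0.15, 0.34, 0.25 and 0.14 for the first 4 of these, to 0.17 for Dexa 200 mg against dICB and to 0.16 for both doses; background subtraction moved it to 0.13 between the doses.

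For Dexa 200 mg against isotype (84 genes), the count was 166 with housekeeping gene factors (44 of the 84), 29 with the code as covariate (26), 148 with samples coded ICI7 (70), 181 with only the groups compared (84) and 169 with both samples that stood apart left out (84). Single omissions gave 0 to 96. Its 2 lists became 0 with camera and an estimated correlation, 0 with samples coded ICI7, 11 with housekeeping gene factors and 4 with positive control factors, and 0 to 2 with single samples left out. Over 21 alternatives the adjusted p of the macrophage list ran from 6.48e-06 to 0.404 (16 passed) and that of the dendritic cell list from 0.00238 to 0.404 (15 passed). For dICB against isotype (0 genes), the count was 30 with DESeq2, 45 with housekeeping gene factors, 2 with no filter, 1 with the replicate block, 4 with positive control factors, 2 with background subtracted and limma, 6 with both samples that stood apart left out, and 0 to 42 with single omissions; its 0 lists became 2 with camera and the preset correlation, 8 with housekeeping gene factors and 0 to 2 with single omissions.

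For Dexa 10 mg against dICB, samples coded ICI10 alone are left aside, as they hold only replicate 2 at 10 mg, which stood apart. The 0 genes of this comparison became 0 to 1 with single omissions, and its 0 lists 3 with the preset correlation. For Dexa 200 mg against dICB they became 3 genes with DESeq2, 1 (Ccl17) with the replicate block and 0 to 8 with single omissions, and 5 lists with the preset correlation. For both doses they became 2 genes with DESeq2 and 0 to 24 with single omissions, and 3 lists with the preset correlation. Between the doses they became 2 genes with DESeq2, 7 with samples coded ICI7 and 2 with both samples that stood apart left out, and 1 list with the preset correlation. For Dexa 10 mg against isotype they became 4 genes with DESeq2, and 4 lists with the preset correlation, 1 with samples coded ICI7 and 1 with both samples that stood apart left out. Single omissions gave 0 genes in the last 2 of these and 0 lists in all comparisons but the 2 of the paragraph before.

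The replicate number did not pair the samples: over 18 pairs with the same number the correlation of deviations ran from -0.39 to 0.29, 4 of 18 were over 0.1, and 4 of 12 samples correlated best with their own number. With the number as a replicate block 84 genes passed for Dexa 200 mg against isotype, 77 of them shared, and apart from the single genes above no count moved by over 1.5 times.

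Log2 fold changes that changed sign were small or rested on a sample that stood apart. With both such samples left out, S100a8 was at 0.40 for both doses, 0.44 for 10 mg and 0.36 for 200 mg against dICB and -0.064 for dICB against isotype; Lcn2 was at 0.68 for both doses and -0.085 for dICB against isotype; Cxcl2 was at 0.12 for both doses and 0.26 for 10 mg. Pdcd1 was then at -0.14 for both doses, -0.23 for 10 mg against dICB and 0.18 between the doses, where Cd274 was at 0.42 and Ctla4 at 0.066. With housekeeping gene factors Pdcd1 was at 0.19, 0.24 and 0.30 for dICB, 10 mg and 200 mg against isotype, 0.12 for 200 mg against dICB and 0.060 between the doses; Ctla4 was at 0.089 for 200 mg against isotype and 0.13 between the doses, and Cd274 at 0.20 between the doses. With positive control factors Pdcd1 was at 0.22 and 0.022 for 10 mg and 200 mg against isotype and 0.15 for 200 mg against dICB, and Cd274 at 0.036 between the doses. With samples coded ICI7 alone Pdcd1 was at 0.57, Ctla4 at 0.41 and Cd274 at 0.25 between the doses, and Pdcd1 at 0.12 for 200 mg against isotype. With samples coded ICI10 alone Cd274 was at 0.34 for 10 mg and 0.064 for both doses against dICB, and with the code as covariate at 0.085 and 0.0098, with Pdcd1 at 0.075 for 200 mg against dICB. Pdcd1 was at 0.0064 for 10 mg against isotype with only the groups compared and at 0.011 for 200 mg against dICB with no filter. Between the doses Cd274 was at 0.061 with background subtracted and limma and at 0.019 with the replicate block.

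With single samples left out, ranges were -4.75 to 0.29 for S100a8 and -4.69 to 0.55 for Lcn2 and -4.67 to 0.047 for Cxcl2 in both doses against dICB, -4.82 to 0.22 and -4.67 to 0.36 for S100a8 in 10 mg and 200 mg, -4.62 to 0.093 and -4.72 to 0.00088 for Cxcl2 there, and -0.055 to 4.96 for S100a8 and -0.070 to 5.14 for Lcn2 in dICB against isotype. Each changed sign without dICB replicate 1. Ranges without a change of sign were -0.53 to -0.05 for Pdcd1 and 0.092 to 0.42 for Ctla4 in dICB against isotype. Ctla4 also ran from -0.79 to -0.37 for 10 mg, -0.92 to -0.54 for 200 mg and -0.81 to -0.45 for both doses against dICB, and from -0.55 to -0.19 and -0.66 to -0.29 for 10 mg and 200 mg against isotype. Cd274 ran from -0.70 to -0.033 for 10 mg, -0.46 to -0.17 for 200 mg and -0.49 to -0.14 for both doses against dICB. For Pdcd1 they were -0.10 to 0.40 for both doses, -0.19 to 0.53 for 10 mg and -0.24 to 0.27 for 200 mg against dICB, -0.45 to 0.21 and -0.48 to 0.027 for 10 mg and 200 mg against isotype, and -0.48 to 0.18 between the doses, where Cd274 ran from -0.26 to 0.41 and Ctla4 from -0.34 to 0.067. No code held both dICB and isotype, so that comparison had no fit within a code, and a prior count of 16 enters list tests only. Where an omission or a code left 1 sample in a group, it was assumed to vary like the others. Depth limits genes near background, whose folds are understated.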

Other observations

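The fits with housekeeping gene factors and with the code as a covariate were fixed before the data were examined. Their use here as tests of scaling and sample code was chosen after the results had been seen. The same holds for the test of tumour share, the comparison of list scores and the positive control factors. The counts over other splits of the samples were chosen before. Cfd, a serine protease of fat cells, was high in 1 sample of each Dexa group: 1510 normalised counts in Dexa 10 mg replicate 3 and 1587 in Dexa 200 mg replicate 1, against 16.9 to 225.5 in the other 10 samples. The log2 fold change of 4.18 ± 1.69 for both doses against dICB thus rested on those samples. Mmp9 held 31.0 to 63.3 counts in the 6 samples given Dexa and 74.1 to 156 in the other 6. That grouping of all samples was seen in the values and has no test of its own.

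For the genes that fell under Dexa 200 mg against isotype scaling stays open. Of the 39 that are not housekeeping genes, 5 still passed with housekeeping gene factors (Cxcl15 -1.64, Il11 -1.13, C1qbp -0.65, Myc -0.54 and Nup107 -0.51). Their median moved from -0.88 ± 0.23 (median SE) to -0.35 ± 0.24, so the calls ended because the folds shrank while the spread stayed, and 2 passed with positive control factors (median -0.55). All 39 were still lower with housekeeping gene factors, but they had been chosen for being low. Both sets of factors moved the median of all genes up, to 0.55 and 0.34, which shrinks any fall whatever its cause. The lost calls therefore cannot tell whether scaling made up these falls. Whether housekeeping RNA itself differed between the groups stays open too.

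For the genes that rose in that comparison scaling stays open: 39 of 39 passed with housekeeping gene factors and with positive control factors, but both moved the median of all genes up, to 0.55 and 0.34, and so could not have ended a rise. For the macrophage list it is argued against as the whole cause, since the scaling of a sample cancels between 2 scores: the macrophage score rose by 0.93 and the endothelial score was at -0.17, a gap of 1.10 with an SD of 0.14. For that list the same gap argues against a lower share of tumour cells in the tissue as the whole cause, but only under an assumption. It is that a lower share would raise the markers of other cell types alike, which was not tested. The macrophage list had been seen to rise, and the endothelial score was the lowest of the non-epithelial scores given here, so other gaps are narrower. T cell, NK, mast cell, B cell, fibroblast, neutrophil, cytotoxic and dendritic cell scores lay at 0.03, 0.03, 0.14, 0.17, 0.21, 0.22, 0.38 and 0.47. A share of the rises stays open to a lower tumour share, as the epithelial score was at -0.37. The sample code as a batch stays open for the 84 calls. With it as a covariate their median log2 fold change, signed by direction, was 1.01 ± 0.30 against 0.99 ± 0.25 without it. All 84 kept their direction, and 26 still passed with the wider error. The code effect came only from splits of 2 samples against 1 within each Dexa group. At 10 mg the sample coded ICI10 was replicate 2, which stood apart. The 84 had been picked by their difference in these same samples, which favours a kept direction and size. A hypothesis that macrophages were more numerous or more active in these samples may account for the rises of macrophage genes, but no group had Dexa alone, so the antibodies and Dexa were not separated. Nos2 and Arg1 were also higher under dICB alone, by 2.11 and 1.66, without passing, and a difference of the 2 effects was tested only as Dexa 200 mg against dICB, in which 0 genes passed in edgeR and DESeq2 passed 3 (54 at an unadjusted p under 0.05 in edgeR).

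Other splits of the same samples show how often a count as large arises. For Dexa 200 mg against isotype, 1 of 10 splits, the real one, gave as many genes, 84 against at most 0 in the others, and likewise for lists, 2 against 0. With 3 samples against 3 there are 10 splits, too few for a share under 0.1. For the other comparisons of 3 against 3 the real counts were 0 and 10 of 10 splits gave as many, which a count of 0 makes certain. The highest count of genes in another split was 0 for dICB against isotype, 1 for Dexa 10 mg against dICB, and 0 for Dexa 200 mg against dICB, for the doses against each other and for Dexa 10 mg against isotype. The highest counts of lists were 1, 2, 2, 0 and 0 in that order. For both doses against dICB the real counts were 0 genes and 0 lists as well, so that 84 of 84 splits were bound to give as many and show nothing about chance. One of them gave 37 genes, and the highest count of lists was 3; the split with 37 genes put dICB replicate 2 with the Dexa samples and Dexa 10 mg replicate 2 with dICB replicates 1 and 3. It was the largest of the 84, and whether the samples have a structure apart from the groups was not tested.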
